A study of Homo sapiens with 6 samples.

How the data were processed

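RNA from 6 cultures of LN229 cells was sequenced, 3 controls and 3 with GDH1 knocked down for 24 h, which the series design describes as biological replicates. The group of each library came from its genotype label and its replicate number from its title. The labels do not say whether the 3 knockdown libraries share 1 siRNA. The deposited file was 1 table of the whole series with whole-number counts per gene row and no normalization, as its values show. Reads were mapped to GRCh38.p14, per the submitters' processing notes, and the aligner, the counting tool and the strand setting are not given in the sources used here. Of the rows, 4956 were newly assembled loci with no gene name (1.23 ± 0.00439% of control counts and 1.25 ± 0.05% of knockdown counts). They stayed in the library totals and tests and were not named. The table keeps separate rows for the copies of a gene on alternate or patch sequences: 1634 symbols had several rows, 4854 rows in all, with 5.29 to 5.61% of the counts of a library. How reads were shared between such copies varied between libraries (LDHA had 26559, 34221 and 29604 counts in its first row in controls and 44914, 35475 and 43398 in its second), so values of these symbols are uncertain. They include PCK2, SESN2, CRIM1 and SQSTM1 among the genes named. A gene list was represented by the row of each symbol with the highest mean count.

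From these counts, rows with too few counts were removed with filterByExpr, which left 16598, libraries were scaled by the trimmed mean of M values (TMM), and groups were compared with the quasi-likelihood F-test of edgeR 4.0.16 (glmQLFit with robust fitting, glmQLFTest, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested rows and a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of F. CPM values are TMM-scaled, and log2 CPM used a prior count of 2. A call thus measures the difference against the spread between 3 cultures, and the precision of single values follows from totals of 31201100 to 35619614 counts. The biological coefficient of variation was 0.149. Counts were simulated from the means, library sizes and spread of this comparison (16598 rows, 200 changed, 50 at each size). The test called 4.0% of genes changed by 0.3 on the log2 scale, 50% at 0.5, 84% at 1 and 100% at 2. It also made 16 false calls, a larger share of its calls than the nominal 0.05. The simulation had fewer changed rows than the 3454 called in the data, so its adjusted threshold was stricter.

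Before the data were examined, 32 gene lists, the tests, the rule for naming genes and most of the other settings were fixed. The lists cover glutamine and glutamate metabolism, the tricarboxylic acid cycle, glycolysis, nuclear and mitochondrial oxidative phosphorylation genes, ATF4, the unfolded protein response, NRF2, hypoxia, 2-oxoglutarate-dependent chromatin dioxygenases, EGFR and ERK, PI3K and mTOR, both parts of the cell cycle, p53, apoptosis, cholesterol, fatty acids, nucleotides, extracellular matrix, YAP/TAZ, interferon, NF-kappaB, autophagy, glioma stem markers, ribosomal proteins, histones, and markers of neurons, oligodendrocytes, leukocytes, endothelium and epithelium. The 30 lists with at least 5 tested members were tested with camera (limma 3.58.1, inter-gene correlation preset at 0.01), adjusted over the lists. In simulated counts with no list effect, camera called 0 of 30 lists, but those counts had no correlation between genes, and a planted shift of 0.3 in 25 genes gave p = 3.70e-31. Genes were named by rule: GLUD1 and GLUD2, the 10 largest rises and the 10 largest falls among called genes with an average log2 CPM of at least 3, all 3 knockdown libraries beyond all 3 controls and an ordinary symbol, and per list up to 4 members with the smallest p, or the most abundant member where none passed. Some genes that this rule names are not reported here. Members named only to complete a count of 5 or fewer were chosen after their values were seen, as were EGFR, SLC38A5, CA9, ND5, ND6, SREBF1, SREBF2 and the genes that open the other observations.

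The settings fixed in advance were scaling by relative log expression or upper quartile, no filter or a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library in turn, an adjusted p under 0.01, glmTreat against a 1.2-fold change, camera with an estimated correlation, and fry. Added after seeing the data were the sum of all rows of a symbol, lists without shared members, and a correction for GC content and transcript length. The correction subtracted, per library, a loess surface (span 0.5) of the deviation of log2 CPM over GC content and log length, taken from the GENCODE protein-coding transcripts of GRCh38, which covered 85.4% of tested rows and 100% of list members. In simulated counts with a planted GC trend in the knockdown libraries (16598 rows), the correlation of fold change with GC content went from -0.67 to -0.01 and false calls from 359 to 17. Gene positions are those of RefSeq on GRCh38.p14, the build of the table. No pair of libraries agreed within sampling noise (chi-square per degree of freedom 9.81 to 13.6 between controls, 14.6 to 40.8 between knockdown libraries), so none was treated as 1 library deposited more than once. This does not show that the libraries came from separate cultures, which rests on the series design.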

Results

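Total RNA of LN229 cells, an established human glioblastoma line grown as an adherent culture, was sequenced in 6 libraries. In 3 of them GDH1 had been knocked down by transfected small interfering RNA (siRNA) for 24 h, and the other 3 were controls that the labels call wild type. The protocol also mentions a mixture abbreviated NC for the control dishes, and whether control cells met the transfection reagent is not given in the sources used here. The deposited table held 28196 gene rows of whole-number counts, and 5109 of them were 0 in every library. Totals were 34452724, 31201100 and 32753013 counts in control replicates 1 to 3 and 35619614, 33355207 and 34862691 in knockdown replicates 1 to 3. The question was which transcripts differ when GDH1 is depleted. GDH1 is glutamate dehydrogenase 1, the mitochondrial enzyme that converts glutamate to 2-oxoglutarate, and its gene is GLUD1.

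GLUD1 itself, which spans positions 87050202 to 87094843 of chromosome 10 (GRCh38.p14), was lower in every knockdown library. It had 3048, 2689 and 2813 counts in the control libraries and 727, 877 and 933 in the knockdown libraries. These were 86.4 ± 1.26 CPM (counts scaled to library size) in controls and 24.6 ± 3.31 CPM in the knockdown (mean ± SD, n = 3 each), so that 28.5% of the control level was left. The log2 fold change was -1.81 with a standard error (SE) of 0.10, and the adjusted p was 1.14e-05 in edgeR's quasi-likelihood test. A two-sided exact permutation test of log2 CPM gave p = 0.1, the smallest that 3 libraries against 3 allow. GLUD2, a near-identical retrocopy on chromosome X (121047610 to 121050094), had 0 to 12 counts per library in its 2 rows. It was too low to test, and reads shared with GLUD1 leave both values uncertain to that extent.

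Across the transcriptome, 3454 of 16598 tested gene rows (20.8%) passed an adjusted p of 0.05, 1779 of them higher and 1675 lower in the knockdown. Most changes were small: the median absolute log2 fold change of the called rows was 0.51, and 565 rows changed at least 2-fold, 305 upward and 260 downward. Control and knockdown libraries did not overlap for 40.3% of the tested rows, where chance gives 10%. The count of calls depended on single libraries. It was 1731 without control replicate 1, 1726 without control replicate 3 and 1797 without knockdown replicate 2, but 5615 without knockdown replicate 1.

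**Figure D1:**
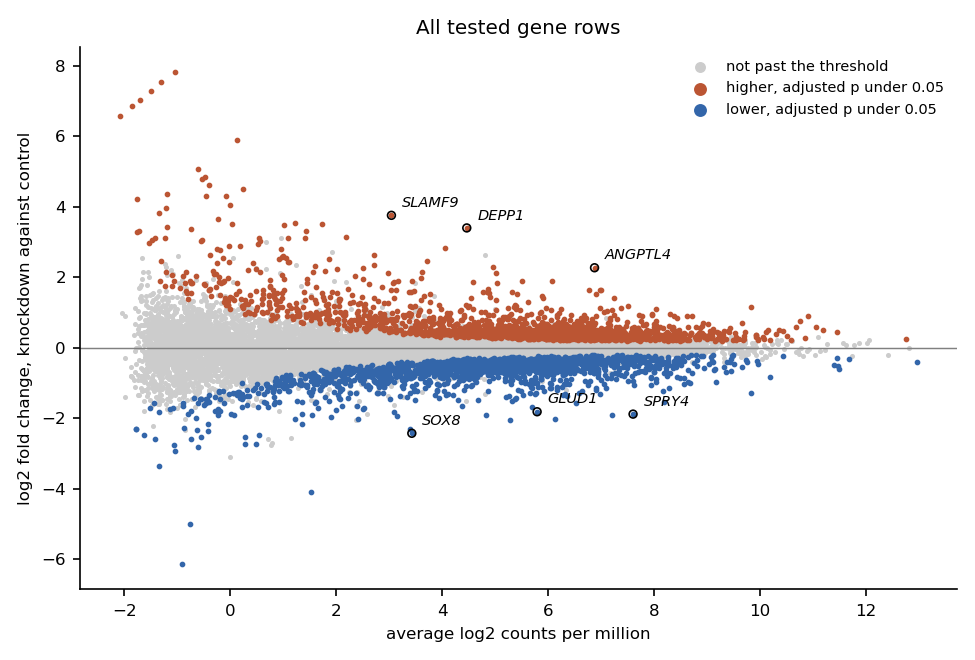
Each point is 1 of 16598 tested gene rows, with its average log2 CPM on the horizontal axis and its log2 fold change of the knockdown against control on the vertical axis. Colours mark the 1779 rows that were higher and the 1675 that were lower at an adjusted p under 0.05, and circles mark 6 named genes, among them GLUD1 at -1.81.

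Fold changes followed the GC content of the transcripts. Among genes with a reference transcript, split into 5 bins of equal size by GC content, the lowest bin had a median log2 fold change of 0.15 and the highest had -0.28 (Spearman correlation across genes -0.44, where genes are not independent replicates). This trend did not separate the groups. Among genes with an average log2 CPM of at least 3, the gap between the lowest and the highest bin, relative to the control mean, was -0.12, 0.15 and -0.03 in control replicates 1 to 3. It was 0.06, 0.48 and 0.77 in knockdown replicates 1 to 3 (two-sided exact permutation p = 0.2, smallest possible 0.1). After each library's trend with GC content and transcript length was removed, an alternative chosen after seeing the data, 2770 rows were higher and 2055 lower, and 2996 rows were called both with and without it.

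**Figure D2:**
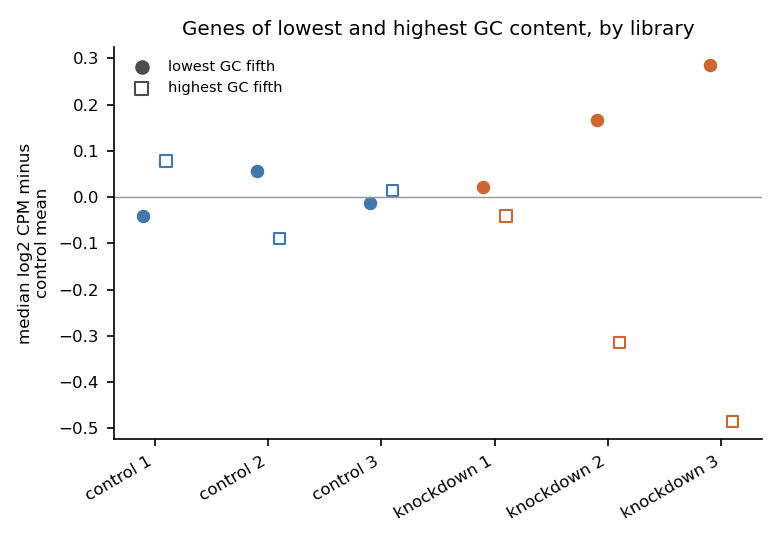
For each library, the median over genes (average log2 CPM at least 3) of log2 CPM minus the mean of the 3 controls is shown for the bin of genes with the lowest GC content (filled circles) and the bin with the highest (open squares), blue for controls and orange for the knockdown. The gap between the symbols was 0.06 in knockdown replicate 1 and 0.77 in knockdown replicate 3, while the controls lay between -0.12 and 0.15.

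The genes that rose most included SLAMF9, DEPP1 and ANGPTL4. SLAMF9, a leukocyte surface receptor gene, rose from 1.12 ± 0.323 to 15.2 ± 2.65 CPM, a log2 fold change of 3.76 (SE 0.23, adjusted p = 1.27e-05, edgeR). DEPP1, a FOXO-responsive gene, rose from 3.80 ± 1.17 to 40.3 ± 7.96 CPM (log2 fold change 3.40). ANGPTL4, which encodes a secreted inhibitor of lipoprotein lipase, rose from 40.3 ± 7.67 to 195.2 ± 44.4 CPM (log2 fold change 2.27, adjusted p = 7.53e-04). HILPDA, a lipid droplet protein gene induced by hypoxia, rose by 2.13 on the log2 scale and STC1, which encodes a secreted glycoprotein, by 1.90. PTGES, whose enzyme makes prostaglandin E2, rose by 1.90, as did the urea transporter gene SLC14A1. The keratin gene KRT80 rose by 2.45, the interleukin receptor gene IL7R by 2.16 and MICAL2, whose product oxidises actin, by 1.89.

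The steepest falls included SOX8, CHAC1 and EGR1. SOX8, a glial transcription factor gene, fell from 18.1 ± 0.865 to 3.37 ± 0.846 CPM (log2 fold change -2.42, SE 0.18, adjusted p = 2.42e-05, edgeR). CHAC1, which encodes a glutathione-degrading enzyme, fell from 17.3 ± 1.78 to 3.53 ± 0.942 CPM (-2.30). The immediate early gene EGR1 fell from 62.8 ± 3.61 to 15.4 ± 1.84 CPM (-2.03). SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling, fell from 306.8 ± 2.35 to 83.4 ± 1.15 CPM (-1.88, SE 0.06, adjusted p = 6.37e-07). GDF15, a stress-induced cytokine gene, fell from 232.3 ± 7.94 to 62.2 ± 13.4 CPM (-1.90). The myelin-associated glycoprotein gene MAG fell by 1.91 on the log2 scale, LGI4, which acts in glial development, by 1.81, the homeobox gene TLX1 by 1.94 and the transcriptional co-regulator gene CITED4 by 2.03. GLUD1 was among these 10 falls. For all of these genes the 3 knockdown libraries lay on the same side of the 3 controls, as the rule for naming them required, and each kept its call with any 1 library left out.

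**Figure D3:**
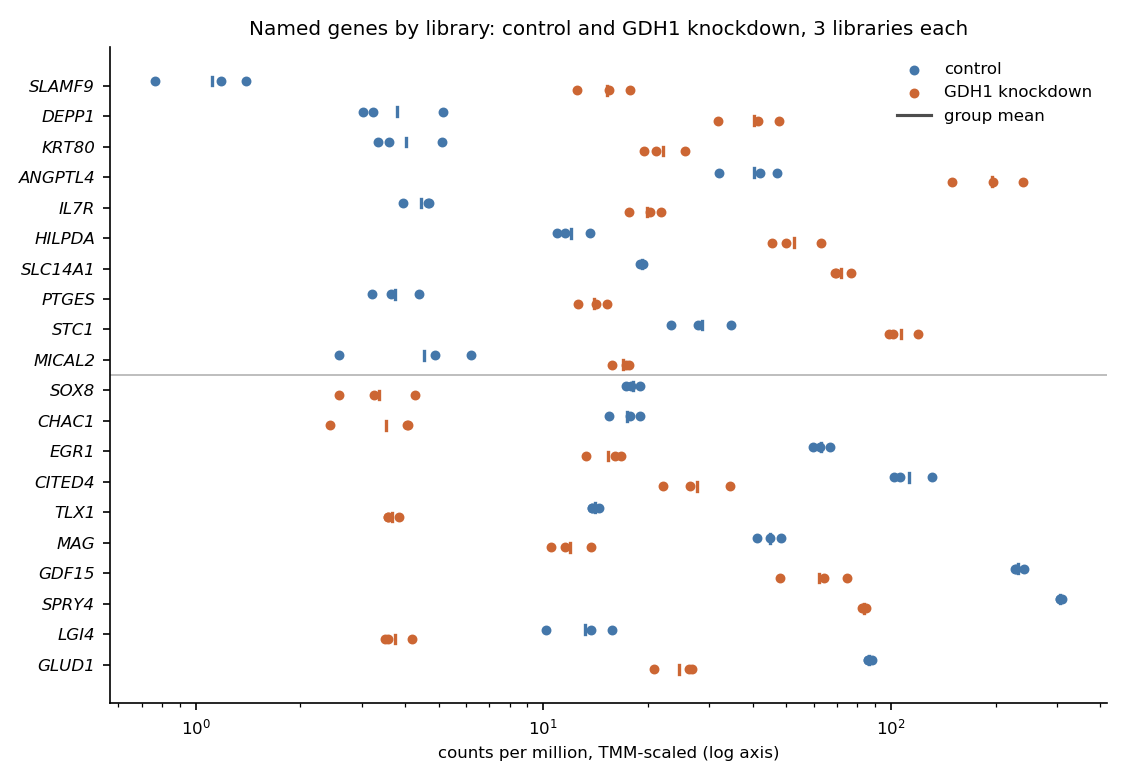
CPM, on a log axis, of the 10 genes that rose most (upper part) and the 10 that fell most (lower part) under the naming rule, with 1 point per library (blue for the 3 controls, orange for the 3 knockdown libraries) and a short bar at each group mean. SLAMF9 had means of 1.12 and 15.2 CPM, and SPRY4 of 306.8 and 83.4 CPM.

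Genes of cholesterol synthesis fell together. Of 24 measured members of the list of cholesterol synthesis genes and SREBP2 targets, 20 fell, 0 rose and 4 did not pass the test, and 21 passed when adjusted over the list alone, all lower. The median log2 fold change was -0.78. HMGCS1, an enzyme gene of the mevalonate pathway, fell from 78.6 ± 3.32 to 24.8 ± 3.06 CPM (-1.66). DHCR7, which acts in the last steps of the pathway, fell by 1.37 on the log2 scale and INSIG1, a sterol-sensing regulator, by 1.32. The list was called by camera with a preset correlation between genes of 0.01 (adjusted p = 1.17e-34), and it was the 1 call that held with an estimated correlation (adjusted p = 0.0046).

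Fatty acid genes were mostly lower. Of 23 measured members of the list of fatty acid synthesis genes and SREBP1 targets, 13 fell, 2 rose (ACSL1 and ME1) and 8 did not pass, with 14 lower and 2 higher when adjusted over the list alone. ME1 lost its call without control replicate 1 or 2 or knockdown replicate 2, which left 1 higher. The desaturase gene SCD fell from 348.6 ± 10.8 to 177.4 ± 13.2 CPM (log2 fold change -0.97), FADS2, another desaturase gene, by 1.32 on the log2 scale and ACSS2, whose enzyme makes acetyl-CoA from acetate, by 1.11. The genes of the regulators SREBF1 (-1.14) and SREBF2 (-1.06), chosen after their values were seen, were called. They are already in the counts, SREBF1 as a member of this list and SREBF2 of the cholesterol list. With the GC and length correction they were at -0.80 and -0.88, both called. The list was called (camera adjusted p = 1.73e-08), with a median of -0.35 (adjusted p = 0.066 with an estimated correlation). Without MVD, the member shared with the cholesterol list, the median was -0.33.

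The amino acid stress genes driven by ATF4 were mostly lower. Of 35 measured members, 25 fell, 3 rose (STC2, VLDLR and ATF3) and 7 did not pass, with 28 lower and 3 higher when adjusted over the list alone. ASNS, the asparagine synthetase gene, fell from 180.1 ± 19.5 to 72.9 ± 3.85 CPM (log2 fold change -1.30, SE 0.09, adjusted p = 1.75e-05, edgeR). The folate enzyme gene MTHFD2 fell by 1.13 on the log2 scale and PHGDH, the first enzyme gene of serine synthesis, by 1.04. STC2, a secreted glycoprotein gene, rose by 1.48. Camera gave an adjusted p of 7.22e-22 with a median of -0.66 (adjusted p = 0.063 with an estimated correlation). Of the 31 members not shared with the glutamine list, 22 fell and 3 rose. Of 24 measured p53 targets, 6 fell and 1 (FAS) rose, with 8 and 3 when adjusted over the list alone, and GDF15, which both lists hold, had the smallest p. That list was not called (camera adjusted p = 0.12), but was without knockdown replicate 3 (0.045). Of its 22 members not shared with the ATF4 list, 4 fell and 1 rose. FAS lost its call without control replicate 1 or 2 or knockdown replicate 2 or 3, which left 0 higher, and without knockdown replicate 1 the count was 3. With the GC and length correction FAS was at 0.26 and lost its call (adjusted p = 0.077), while 3 other members were higher and the list's median went from -0.06 to -0.01. The count higher was 2 with upper quartile scaling, either other filter, DESeq2, the replicate block or copies summed, and the block also called the list (adjusted p = 0.049).

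Genes of glutamine and glutamate handling, the pathway around GDH1, went both ways. Of 33 measured members, 9 fell, 5 rose and 19 did not pass, with 12 lower and 6 higher when adjusted over the list alone. Beside ASNS, the falls included PSAT1 (-0.85), which uses glutamate as amino donor, the proline synthesis gene PYCR1 (-0.91) and SLC1A5 (-0.79), a glutamine transporter gene. The 5 that rose, chosen after their values were seen, were GFPT2, SLC38A5, GCLM, GOT2 and GFPT1. Among them SLC38A5, another glutamine transporter gene, had a log2 fold change of 2.56 (SE 0.39) at a low level, from 0.577 ± 0.311 to 3.43 ± 0.691 CPM. The list's median was 0.04, its mean -0.07 and camera's direction down (adjusted p = 0.10, 0.029 with no filter on low counts, 0.047 with the replicate block and 0.013 with the GC and length correction, where 9 were higher, 11 lower and the median -0.08). With 1 library left out the median ranged from -0.06 to 0.02. Of the 29 members not shared with the ATF4 list, 6 fell and 5 rose. The 9 lower members became 5 without control replicate 1 or knockdown replicate 2.

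Hypoxia-response genes rose. Of 25 measured members, 20 rose, 0 fell and 5 did not pass, with 21 higher and 1 lower when adjusted over the list alone, and the median log2 fold change was 0.68. INSIG2, which holds back sterol synthesis, rose from 24.8 ± 2.35 to 57.8 ± 6.59 CPM (1.22). ERO1A, an oxidase gene of the endoplasmic reticulum, rose by 1.14 on the log2 scale, the mitophagy receptor gene BNIP3 by 1.01 and the transcription factor gene BHLHE40 by 0.65. CA9, chosen after its value was seen, had the largest fold change of the list (2.65, SE 0.64) but an adjusted p of 0.052. It was called without control replicate 2 (0.033) or 3 (0.0017), with the stricter filter (0.046), DESeq2 (6.75e-04), limma-voom (0.016), the GC and length correction (0.034) and copies summed (0.038), and it was at 0.10 to 0.17 without any 1 of the other libraries. The camera test of the list gave an adjusted p of 3.90e-20 (adjusted p = 0.12 with an estimated correlation). Without knockdown replicate 1, 19 members were higher and 1 was lower, and DESeq2 also called 1 lower. Of the 21 members not shared with the glycolysis list, 17 rose and 0 fell.

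Of 25 glycolysis genes, 11 rose, 1 (PFKFB2) fell and 13 did not pass, with 11 higher and 2 lower when adjusted over the list alone. The enolase gene ENO2 rose from 83.3 ± 8.01 to 220.4 ± 31.4 CPM (1.40), the kinase genes PGK1 and PFKP by 0.69 and 0.76 on the log2 scale and the glucose transporter gene SLC2A3 by 0.84. This list was called as well (camera adjusted p = 2.78e-06, median 0.21), but not with an estimated correlation (adjusted p = 0.32). The GC and length correction gave 17 higher members, 1 lower and a median of 0.33. Without the members shared with the hypoxia list, 8 of 21 rose and the median was 0.18. PFKFB2 lost its call without any 1 library other than knockdown replicate 3, and with upper quartile scaling (adjusted p = 0.053). The number lower was 2 without knockdown replicate 1 or with DESeq2, and 0 without any 1 control or knockdown replicate 2 or with upper quartile scaling.

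The lists of nuclear genes of mitochondrial metabolism were not called. Of 29 tricarboxylic acid cycle genes, 8 rose and 3 fell, with 9 and 4 when adjusted over the list alone (camera adjusted p = 0.24, median 0.07, or 0.13 with the GC and length correction). The dehydrogenase subunit gene DLD and the fumarase gene FH both rose by 0.39 on the log2 scale and the succinyl-CoA synthetase gene SUCLA2 by 0.46. PCK2 (-1.09, and -1.07 with its 2 rows summed), IDH1 (-0.42) and IDH2 (-0.34) fell, of which the isocitrate dehydrogenase genes were chosen after their values were seen. The number higher was 5 without any 1 control and 4 without knockdown replicate 2. The number lower was 1 without control replicate 2 or 3 or knockdown replicate 2, where IDH1 and IDH2 were not called, and 5 without knockdown replicate 1. With 1 library left out, IDH2 kept its call only without knockdown replicate 1. With the GC and length correction DLD was at 0.24, SUCLA2 at 0.31 and IDH2 at -0.21, all called. Of 51 nuclear oxidative phosphorylation genes, 4 passed (NDUFA9, CYCS and COX7B higher, NDUFA2 lower) and 0 passed when adjusted over the list alone (10 had an unadjusted p under 0.05, and over all genes DESeq2 called 6 and limma-voom 4). All 4 lost their calls without control replicate 1, control replicate 3 or knockdown replicate 2, where the list had 0 higher and 0 lower, and NDUFA9 then had adjusted p values of 0.054, 0.067 and 0.067. Without control replicate 2 the list had 0 higher and 2 lower, and without knockdown replicate 1 it had 4 higher and 9 lower. COX7B lost its call with the GC and length correction (adjusted p = 0.060). There the list had 5 higher and 4 lower, and 3 were lower with the replicate block or copies summed and 2 with DESeq2. Its median was 0.01, its mean -0.03 and camera's adjusted p 0.90.

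Transcripts encoded by the mitochondrial genome were lower, unevenly. All 13 mRNAs had a fold change below 0 (12 with upper quartile scaling, where ND6 was above 0), and 5 of them passed (COX3, ATP6, COX1, CYTB and ATP8), or 9 when adjusted over the list alone. Their share of all counts was 3.65 ± 0.262% in controls and 2.91 ± 0.220% in the knockdown (n = 3 each, two-sided exact permutation p = 0.1, the smallest possible). COX3 fell from 3492 ± 227.0 to 2312 ± 128.0 CPM (log2 fold change -0.59, adjusted p = 4.55e-04, edgeR) and ATP6 by 0.52 on the log2 scale. ND5 (-0.10) and ND6 (-0.01), chosen after their values were seen, did not pass, and ND6 was at 0.0041 with upper quartile scaling, 0.03 without control replicate 2, 0.04 without knockdown replicate 1 and 0.0047 without knockdown replicate 2. With the GC and length correction both passed, ND5 at -0.19 (adjusted p = 0.0024) and ND6 at -0.12 (adjusted p = 0.033). The list was called (camera adjusted p = 2.33e-04, median -0.23) (adjusted p = 0.46 with an estimated correlation). The count of mRNAs that passed was 3 without control replicate 2 or 3 or knockdown replicate 2, 8 without knockdown replicate 3, with DESeq2, the replicate block or copies summed, and 12 with the GC and length correction (median -0.35).

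Genes that answer to the EGF receptor and ERK, most of them feedback inhibitors and immediate early genes, were lower on balance. Of 34 measured members, 13 fell, 4 rose (SPRY1, DUSP5, JUN and EGFR) and 17 did not pass, with 15 lower and 8 higher when adjusted over the list alone. Beside SPRY4 and EGR1, the ERK phosphatase gene DUSP6 fell from 185.6 ± 7.47 to 112.1 ± 1.70 CPM (-0.73) and DUSP4 by 0.49 on the log2 scale. EGFR itself, chosen after its value was seen, had a log2 fold change of 0.40 (SE 0.11, adjusted p = 0.023, edgeR). It lost its call without control replicate 2 (adjusted p = 0.093), control replicate 3 (0.11) or knockdown replicate 2 (0.088). The camera test gave an adjusted p of 3.81e-06 with a median of -0.25 (adjusted p = 0.066 with an estimated correlation). The median was -0.10 with the GC and length correction, where 7 members were higher. With libraries left out, 2 members were higher without control replicate 2, 1 without control replicate 3 and 7 without knockdown replicate 1.

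Of 26 components of the PI3K, AKT and mTOR pathway, 4 fell (SGK1, EIF4EBP1, AKT2 and PIK3R3) and 3 rose (PIK3CD, RHEB and FOXO3), the same numbers as when adjusted over the list alone (camera adjusted p = 0.51). The kinase gene SGK1 fell by 0.73 on the log2 scale, the translation repressor gene EIF4EBP1 fell by 0.68 (0.32 with the GC and length correction, also called) and PIK3CD rose by 0.88. Without control replicate 1 or 3, 1 was higher, and without control replicate 1, 2 were lower. AKT2 was among those lost there, with an adjusted p of 0.054, while 7 were higher and 9 lower without knockdown replicate 1. The GC and length correction gave 6 higher and 6 lower, and the median went from -0.05 to 0.05.

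YAP/TAZ targets and inflammatory genes contained strong risers. Of 22 YAP/TAZ targets, 9 rose, 1 (RBMS3) fell and 12 did not pass, the same numbers when adjusted over the list alone. The membrane repair gene MYOF rose from 167.0 ± 5.52 to 357.4 ± 13.4 CPM (1.10), IGFBP3, which binds insulin-like growth factors, by 1.65 on the log2 scale and NT5E, the adenosine-producing enzyme gene, by 0.91. CRIM1 had 2 rows in the table: the larger rose by 1.12, the smaller, at 2.02 ± 0.323 CPM in controls, fell by 2.74, and their sum rose by 1.09. The YAP/TAZ list was called (camera adjusted p = 1.36e-08), with a median of 0.18 (0.34 with the GC and length correction) (adjusted p = 0.063 with an estimated correlation). Without knockdown replicate 1, 2 members were lower. There were also 2 lower with the replicate block and with the GC and length correction. Of 23 genes of the NF-kappaB and inflammatory list, 10 rose, 1 (LIF) fell and 12 did not pass, with 12 and 1 when adjusted over the list alone. The chemokine gene CXCL8 rose from 14.5 ± 0.725 to 51.5 ± 5.80 CPM (1.83), PTGS2, the inducible cyclooxygenase gene, by 1.58, BIRC3 by 1.55 and the inhibitor gene NFKBIA by 0.68. Camera gave an adjusted p of 6.43e-06 with a median of 0.32 (adjusted p = 0.12 with an estimated correlation). LIF lost its call without any 1 library other than knockdown replicate 1, where 2 members were lower.

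Of 31 genes of the interferon and double-stranded RNA response, a class that transfected RNA can induce, 4 fell (IFIT2, IFIT3, MX2 and STAT2) and 2 rose (OASL and OAS3), the same numbers when adjusted over the list alone. OASL (0.709 ± 0.408 to 2.23 ± 0.665 CPM) and MX2 (4.44 ± 0.287 to 2.57 ± 0.198 CPM) were at low levels. IFIT2 fell from 25.9 ± 0.0687 to 12.7 ± 2.30 CPM (-1.02) and IFIT3 by 0.72 on the log2 scale. The list was not called (camera adjusted p = 0.82). Its median and mean were 0.06 and 0.04, and camera's direction was down, but up with the replicate block and without control replicate 2 or knockdown replicate 1 or 3. With 1 library left out the median ranged from -0.12 to 0.19. Relative to the control mean, the members averaged 0.20 in control replicate 2 and 0.34 in knockdown replicate 2. They averaged -0.075 and -0.12 in control replicates 1 and 3 and -0.12 and -0.18 in knockdown replicates 1 and 3. The number higher was 0 without control replicate 1 or 3 or knockdown replicate 2 and 1 without control replicate 2, and the number lower was 2 without control replicate 3. With the replicate block 4 were higher, and the median was 0.02 with the GC and length correction. Of 31 extracellular matrix and mesenchymal genes, 6 rose and 6 fell, with 9 and 6 when adjusted over the list alone. The matrix protein gene THBS1 rose from 567.9 ± 18.3 to 1263 ± 70.3 CPM (1.15) and the hyaluronan receptor gene CD44 by 0.44 on the log2 scale, while the transcription factor gene TWIST1 fell by 1.41. Camera did not call the list (adjusted p = 0.38, and 0.013 with the GC and length correction, where 12 were higher, 8 lower and the median 0.08 against 0.03).

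Mitotic genes rose by small amounts. Of 34 G2/M genes, 22 rose, 0 fell and 12 did not pass, with 27 higher when adjusted over the list alone, and all 34 had a fold change above 0. The cytokinesis gene ANLN rose from 378.7 ± 17.7 to 564.4 ± 34.0 CPM (0.58), the spindle checkpoint gene BUB1B and the cytokinesis regulator gene ECT2 each by 0.52 on the log2 scale and the hyaluronan-binding spindle gene HMMR by 0.67. Camera's adjusted p was 3.32e-10, with a median of 0.32 (adjusted p = 0.24 with an estimated correlation). These transcripts are poor in GC (list median 43.3%), and with the GC and length correction the median was 0.22, 29 members were higher and ECT2 was at 0.34. Of these genes, 12 were higher without control replicate 1, 11 without control replicate 3 and 13 without knockdown replicate 2.

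Few genes of G1/S and DNA replication passed. Of 35, 3 rose (RRM1 and RRM2 among them) and 1 (E2F1) fell, with 2 and 0 when adjusted over the list alone (camera adjusted p = 0.999, median -0.02). The ribonucleotide reductase gene RRM1 rose by 0.39 on the log2 scale. Without any 1 control, 1 member was higher and 0 were lower. E2F1 also lost its call without knockdown replicate 2, where 0 were lower, without knockdown replicate 3, and with the GC and length correction (-0.04, adjusted p = 0.62). Without knockdown replicate 1, 7 were lower. In the GC and length corrected fit 6 were higher and 3 lower, with a median of 0.02, and with the replicate block 2 were lower. Of 25 nucleotide synthesis genes, 6 rose and 1 (SHMT1) fell, with 7 and 1 when adjusted over the list alone. The purine synthesis gene PAICS rose by 0.48. Camera's adjusted p was 0.10 (0.040 with the GC and length correction, where 3 were lower and the median was 0.10 against 0.05). The number higher was 2 without control replicate 1 and 3 without control replicate 2 or 3. SHMT1 lost its call without any 1 library other than knockdown replicate 1. Of 22 apoptosis regulators, 6 fell and 1 (BIRC3) rose, with 6 and 3 when adjusted over the list alone (camera adjusted p = 0.51). PMAIP1, a BH3-only gene, fell by 0.49, the survival gene MCL1 by 0.33 and BCL2L11, another BH3-only gene, by 0.55. The number lower was 3 without control replicate 1 or 3 or knockdown replicate 2 or 3, and the number higher was 3 without knockdown replicate 1. The number higher was also 3 with the replicate block or the GC and length correction, where 4 were lower and the median went from -0.06 to -0.02, and 2 with DESeq2 or copies summed.

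Oxidative stress, protein folding and lysosomal genes were mixed. Of 28 NRF2 targets and antioxidant genes, 8 fell and 6 rose, with 10 each when adjusted over the list alone (camera adjusted p = 0.30). The quinone reductase gene NQO1 fell from 1501 ± 27.3 to 843.6 ± 10.6 CPM (-0.83), the reductase gene AKR1C1 by 0.62 on the log2 scale and the cystine transporter gene SLC7A11 by 0.66, while SRXN1, which repairs peroxiredoxins, rose by 0.46. The number lower was 5 without control replicate 1. The GC and length correction gave 13 higher and 11 lower, and the median went from -0.06 to 0.05. Of 20 genes of the unfolded protein response, 4 fell (XBP1, CRELD2, HERPUD1 and SDF2L1) and 0 rose, with 5 lower and 2 higher when adjusted over the list alone (camera adjusted p = 0.17). XBP1, a transcription factor gene of this response, fell by 0.70. HERPUD1 and SDF2L1 lost their calls without control replicate 1 (adjusted p 0.057 and 0.094), which left 2. SDF2L1 also lost its call without control replicate 3 or knockdown replicate 2, and 3 were higher without knockdown replicate 1. Members higher numbered 2 with DESeq2 or copies summed and 1 with the replicate block or the GC and length correction, which moved the median from -0.02 to -0.07. Of 33 autophagy and lysosome genes, 7 fell and 4 rose (LAMP2, SQSTM1, ATG12 and CTSL), with 9 and 5 when adjusted over the list alone (camera adjusted p = 0.22). The autophagosome gene MAP1LC3A fell by 0.84 and the kinase gene ULK1 by 0.66 (0.33 with the GC and length correction, also called). The number lower was 3 without control replicate 1, 2 without control replicate 3 or knockdown replicate 2 and 13 without knockdown replicate 1. The number higher was 2 without any 1 control or knockdown replicate 2, and 7 without knockdown replicate 1.

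Of 24 chromatin dioxygenases, enzymes that use 2-oxoglutarate, 3 rose (KDM3A, TET1 and KDM4C) and 2 fell (KDM4A and PHF2), the same numbers when adjusted over the list alone (camera adjusted p = 0.51). The histone demethylase gene KDM3A, which the hypoxia list also holds, rose by 0.61 on the log2 scale and KDM4A fell by 0.45. The number lower was 1 without control replicate 1 or 3 or knockdown replicate 2, and 4 without knockdown replicate 1. KDM4C had adjusted p values of 0.071, 0.060 and 0.051 without those first 3 libraries. In all, 7 were higher with the GC and length correction, with a median of 0.04 against 0.07.

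Several glial and progenitor genes fell. Of 22 glioma stem and neural progenitor markers, 7 fell and 3 rose (SOX2, CD44 and L1CAM), the same numbers when adjusted over the list alone. The calcium-binding protein gene S100B fell from 429.7 ± 15.5 to 196.8 ± 10.3 CPM (-1.13), FABP7, a fatty acid binding protein gene of radial glia, by 1.45 on the log2 scale and the low-abundance gene MYCN from 8.48 ± 0.999 to 2.11 ± 0.0339 CPM, while SOX2 rose by 0.79. Camera gave an adjusted p of 0.038 with a median of -0.12 (adjusted p = 0.19 with an estimated correlation). The call was lost without control replicate 1 (adjusted p = 0.062), with limma-voom (0.16), with copies summed (0.051) and with the GC and length correction (0.085, median -0.03). Of 7 oligodendrocyte markers, 4 fell (MAG, MBP and SOX10 among them), or 5 when adjusted over the list alone. Their camera test gave an adjusted p of 2.49e-04 with a median of -0.38 (adjusted p = 0.079 with an estimated correlation). The median was -0.08 with the GC and length correction, where SOX10 lost its call (adjusted p = 0.25). Without control replicate 3, 2 were called: MBP (adjusted p = 0.065) and SOX10 (0.071) were not. SOX10 also lost its call without control replicate 1 or knockdown replicate 2.

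Markers of other cell types were few. Of 8 neuron markers, 3 fell (MAP2, NEFL and SNAP25), the same number when adjusted over the list alone (camera adjusted p = 0.071, but 0.017 without knockdown replicate 3, 0.041 with no filter, 0.032 with the stricter filter and 0.010 with the GC and length correction). MAP2 fell by 0.88 on the log2 scale. NEFL and SNAP25 lost their calls without control replicate 1, control replicate 3 or knockdown replicate 2, which left 1. SNAP25 also lost its call without control replicate 2 or knockdown replicate 1, and with upper quartile scaling (adjusted p = 0.053). Of 6 epithelial markers, KRT8 fell (-0.70), with 1 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.73). KRT8 lost its call without control replicate 1 or 3 (adjusted p 0.092 and 0.055), and with the GC and length correction (0.068), where 1 other member was higher and the list's median went from -0.16 to 0.06. Of the 14 microglia and leukocyte markers 2 were expressed enough to test, and of the 10 endothelial markers 4, so neither list was tested.

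Ribosomal protein genes were listed as a check of RNA composition and histone genes as a check of RNA selection. The values below compare the groups and do not show how the RNA was selected before sequencing. Of 39 ribosomal protein genes, 5 rose (RPL7, RPS6, RPL23, RPL4 and RPL5), the same number when adjusted over the list alone, and the median log2 fold change was 0.02 (camera adjusted p = 0.24, and 0.0086 with the GC and length correction, where 18 were higher and the median was 0.12, and 0.046 without knockdown replicate 3). RPL7 rose by 0.35 on the log2 scale and RPS6 by 0.31 (0.19 with the GC and length correction, also called). The count was 2 without control replicate 1 or 3 or knockdown replicate 2 and 3 without control replicate 2, and 2 were lower without knockdown replicate 1 and 1 with the replicate block. Of 30 replication-dependent histone genes in the list, 14 were tested. Of these, 0 passed in edgeR, also when adjusted over the list alone, 1 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. H2BC12, the most abundant tested member, had 11.8 ± 1.12 CPM in controls and a log2 fold change of -0.01 (SE 0.13). The list had a median of 0.28 (camera adjusted p = 0.38), or 0.10 to 0.48 with 1 library left out.

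Camera thus called 12 of the 30 tested lists, 5 higher and 7 lower. Of these calls 1 held with an estimated correlation. That setting also tests against fewer degrees of freedom, so the loss of a call there need not come from correlated members. The estimated correlation was below the preset 0.01 for the glioma stem markers (-0.0085) and the oligodendrocyte markers (-0.15), which lost their calls. It was above 0.01 for the other lists that lost theirs, from 0.014 (EGFR and ERK) to 0.90 (mitochondrial mRNAs). In each of the other splits of the same 6 libraries 3 to 13 lists were also called, but each such split keeps part of the group difference, so that these are not counts without an effect. In these splits edgeR called 0 genes at an adjusted p of 0.05 and 145 to 1587 genes at an unadjusted p under 0.05. The group difference also widens the spread within each side there, so the 0 is not a background rate. The direction of the list medians did not change between TMM, relative log expression and upper quartile scaling, and the median log2 fold change of all tested rows lay between -0.0036 and 0.0094 under these scalings. With 1 library left out, however, the medians of some lists that were not called crossed 0. These were the lists of glutamine metabolism, nuclear oxidative phosphorylation, NRF2, G1/S, extracellular matrix, interferon and epithelial genes.

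**Figure D4:**
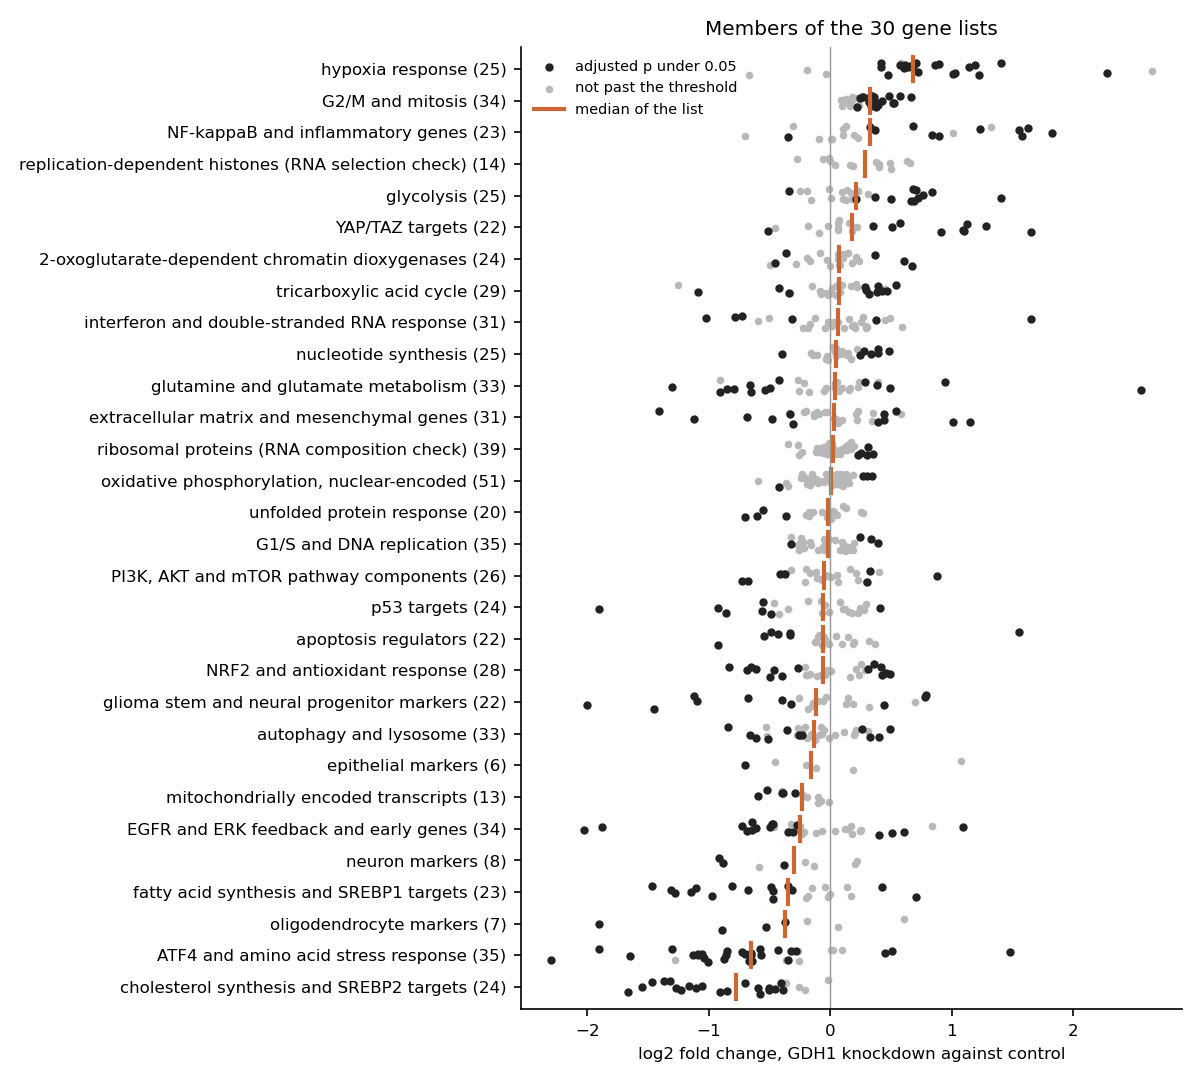
Log2 fold changes of the knockdown against control for the members of the 30 gene lists, with the number of tested members in brackets. Black points passed an adjusted p of 0.05, grey points did not, and orange bars mark the median of each list, from -0.78 for cholesterol synthesis to 0.68 for the hypoxia response.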

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

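The GC and length correction, the sum of copies and the lists without shared members were chosen after the result was seen, and the other settings before. GLUD1 stayed lower and called in every setting run, with log2 fold changes from -1.70 without knockdown replicate 1 to -1.88 without knockdown replicate 3. Under both other scalings, both other filters, DESeq2, limma-voom and the replicate block, the counts of called, higher, lower and at least 2-fold changed genes over all rows stayed within 1.5 times their reported values. Of the 60 counts of higher or lower members of the 30 lists, 0 moved further than that with relative log expression scaling or limma-voom, 2 with upper quartile scaling, 1 with each other filter, 7 with DESeq2, 9 with the replicate block, 5 with copies summed and 20 with the GC and length correction. Among them were the mitochondrial mRNAs lower (8 against 5 with DESeq2, the block and copies summed), members of the interferon list higher (4 against 2 with the block) and of the unfolded protein response higher (2 against 0 with DESeq2). Leaving out control replicate 1, 2 or 3 moved 25, 17 and 24 of the 60 list counts that far. Leaving out knockdown replicate 1, 2 or 3 moved 17, 20 and 5. With 1 library left out, the count of called genes ranged from 1726 (without control replicate 3) to 5615 (without knockdown replicate 1), the count of higher genes from 898 to 2677 and that of lower genes from 798 to 2938. Each of these fits has fewer samples, which lowers power, but the causes of the falls and of the increase were not tested. Knockdown replicates 2 and 3, left without replicate 1, were the most alike (chi-square per degree of freedom 14.6, against 20.4 and 40.8 for pairs with replicate 1). Their GC gaps, 0.48 and 0.77, both lay beyond those of the controls (-0.12 to 0.15). Without knockdown replicate 1 the GC trend thus goes with the groups. Of the 3454 called genes, 3330 were called without knockdown replicate 1, and 0 of these changed sign. The GC and length correction gave 2770 higher genes, and the cause was not tested. An adjusted p under 0.01 left 1508 genes and glmTreat against a 1.2-fold change 1270, by construction. Of the 12 lists called, 1 was called with an estimated correlation, and 20 lists were called by fry, which does not compare a list with other genes.

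Of 1860 values of the 124 other genes under the naming rule, in 15 alternatives, 1780 kept their direction and side of the threshold, 76 lost the call and 4 changed sign. The changes of sign were all of H2BC12, which was never called: 0.28 with the GC and length correction and, with 1 library left out, -0.12 to 0.063. The cause was not tested. Of 449 list values, 418 kept side and direction, 4 lost a call, 13 gained one and 14 changed direction, all of 3 lists never called. The G1/S list turned up with upper quartile scaling (adjusted p = 0.956), the stricter filter (0.978), DESeq2 (0.977), limma-voom (0.999) and the GC and length correction (0.922), and the interferon list with the replicate block (0.965). With 1 library left out, these adjusted p ranged from 0.579 to 0.950 for G1/S, 0.169 to 0.761 for interferon and 0.619 to 0.864 for nuclear oxidative phosphorylation, each of which turned up in some of these fits. The cause was not tested. Summing copies called 223 symbols with several rows, against 161 with a called row before, and 132 of these 161 kept the call and sign. Deviations of same-numbered libraries from their group means correlated weakly over genes (0.17, 0.03 and -0.05), and 1 of 3 pairs correlated best with its own number. Members of the interferon list, however, averaged higher in replicate 2 of both groups than in any other library. A shared replicate effect on some genes is therefore not excluded. The replicate block gave 4055 called genes, and by camera it added glutamine metabolism (adjusted p = 0.047) and p53 targets (0.049). At this depth and with 3 cultures per group, simulated changes of 0.3 on the log2 scale were mostly missed. The simulation had fewer changed rows than were called in the data, so its adjusted threshold was stricter. It therefore does not give the share of such changes missed in the data.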

Other observations

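Several genes outside the tested lists changed as well. They were chosen after their values were seen, as were the GC and length correction, the tests of the mitochondrial transcripts and, for siRNA seeds, the planted shifts and the way the scan is read. HSP90AA1, the inducible cytosolic HSP90 gene, had a log2 fold change of 0.89 (SE 0.07). The prostaglandin receptor gene PTGFR rose beside PTGES and PTGS2, with a log2 fold change of 2.25 (SE 0.22). The gap junction gene GJB1 had a log2 fold change of -1.49 (SE 0.13) and CMTM5 of -1.42 (SE 0.19). CD68, the lysosomal glycoprotein gene used as a macrophage marker, rose from 14.9 ± 1.68 to 27.6 ± 1.27 CPM (n = 3 each, adjusted p = 6.33e-04, edgeR). It belongs to the untested list of microglia and leukocyte markers, of whose 14 members 2 were expressed enough to test. Its rise alone therefore does not point to such cells.

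Knockdown libraries differed in how strongly expression followed GC content, and the library with the least GLUD1 left (replicate 1, 24.1% of the control mean) had the weakest trend. For the 3 strongest list shifts, removing this trend left medians of 0.79 for hypoxia (0.68 before), -0.71 for cholesterol synthesis (-0.78 before) and -0.58 for the ATF4 list (-0.66 before). Camera still called all 3, at adjusted p values of 2.87e-20, 2.28e-48 and 3.62e-30 with the preset correlation, and without the correction hypoxia and the ATF4 list lost their calls with an estimated correlation (adjusted p = 0.12 and 0.063), so the sizes of the medians, not these calls, argue against GC content and length as the whole cause. A difference in the culture dishes, such as cell density, oxygen or serum, stays open, since it would coincide with the groups. An effect of transfection shared by any siRNA also stays open, since the sources used here do not say whether control cells were transfected. Lower GDH1 stays open as the biological explanation, and no test here separates it from these.

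Loss of mitochondrial transcripts was uneven. An equal loss of all 13 mRNAs, which reads taken by other abundant genes would also give, is excluded as the whole cause by the spread of their fold changes (heterogeneity chi-square p = 3.32e-09). A change in the processing or stability of particular mitochondrial transcripts may account for the unevenness as a hypothesis, and it was not tested further.

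Some falls could come from siRNA seeds pairing with 3' untranslated regions of other genes. In a scan of 16108 heptamers over 10556 genes, with GC content, base composition and length as covariates, the most negative association was that of TAATATT (t = -4.48), which does not occur in the GLUD1 transcript and whose genes had a median log2 fold change of 0.083 before the covariates (-0.016 for genes without it), the most negative among heptamers of GLUD1 was AAAATTT (t = -4.37, 3336 genes), and the largest positive t was 4.34. The largest absolute t of each of 100 permutations lay between 3.64 and 4.70, and 11 of them were as large as 4.48. By the bound set before the scan, a t below the permuted maximum counts against seeds, but that bound was set aside after the scan, since shifts of -0.05 planted in genes with 1 of 20 heptamers passed the maximum for 4 of 20 (20 of 20 at -0.1). Off-target pairing cannot be told apart from chance here, because small seed effects would be missed and the siRNA sequence is not given in the sources used here.

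In the 10 splits of the 6 libraries into 3 and 3, the real one gave the most called genes, 3454 against 0 for the highest of the others (1 of 10 splits as large), and likewise 1779 higher, 1675 lower and 565 at least 2-fold against 0. With 10 splits no share under 0.05 can be reached. For lists the real split gave 12 calls and the highest of the others 13, and 3 of the 10 splits gave at least 12. Each of the other splits sets 2 libraries of a group and 1 of the other against the rest, so part of the group difference stays in it. The group difference also adds to the spread within each side there, which lowers the number of calls. The 0 called genes are therefore not a background rate.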
